A study of Mus musculus with 36 samples.

How the data were processed

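RNA was measured on 36 single-channel Affymetrix 3' arrays with 3 for each of 12 groups. A group is 1 of 6 transductions of OT-I CD8 T cells (LacZ control, Ppp2r2d, Egr2, Ptpn2, Arhgap5 or Alk hairpin) under 1 of 2 tissue labels, spleen or tumor. Per the labels, total RNA was taken with Trizol and labelled with biotin in 1 cycle. The submitters' processing notes name RMA, a method that corrects background and summarises the probes of a set. Its version, settings and software are not given in the sources used here. The deposited values are on the log2 scale, as their range and distribution show. How arrays were centred is not stated: array medians lay between -0.48 and -0.23, and the arrays do not share 1 distribution. The scale is therefore known and the centring is not, so levels are compared between arrays and not read as amounts.

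Groups and replicate numbers were taken from the labels. Replicate numbers did not pair the arrays: over 18 pairs of a labelled spleen and a labelled tumor array with the same transduction and number, residual correlations lay between -0.24 and 0.24, and 4 exceeded 0.1. No 2 arrays were identical. Of the probe sets, 34945 carried 1 symbol, 932 several and 9211 were not listed with a gene, and 64 of the array's sets were controls. Each gene was represented by the probe set with the highest mean over the 36 arrays, which gave 18193 genes, 9010 of them with several probe sets. Of these symbols 18032 were named in the reference (assembly GRCm38.p6), used only for names and for which genes neighbour each other.

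Differences were fitted in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). lmFit took 1 coefficient per group over all 36 arrays, which left 24 residual degrees of freedom, and eBayes added 6.75 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes in each of 16 comparisons. These were labelled tumor against labelled spleen in LacZ, each hairpin against LacZ under each label, and 5 tissue differences (interaction terms). The comparisons share the LacZ arrays, so those against LacZ under 1 label are not independent of each other. All tests are two-sided.

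The 26 gene lists cover T cell identity, naive and memory T cells, inhibitory receptors and exhaustion, cytotoxic effectors, cytokines and chemokines, homing and residency, cell cycle, apoptosis, immediate early response, anergy and receptor brakes, interferon response and JAK-STAT targets. They also cover glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, the unfolded protein and integrated stress response, heat shock, PP2A subunits and markers of melanocytes, myeloid cells, neutrophils, B cells, dendritic cells with MHC class II, erythroid cells, stroma with endothelium, and CD4 and NK cells. Of 478 genes asked for, 439 were measured, and 4 pairs of lists share 1 or 2 genes. Lists were tested with limma camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with the correlation estimated from the residuals (given as "estimated"). Members were also counted at a p adjusted over the list alone.

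The groups, the fit, the lists, the named-gene rule and most alternative settings were chosen before the data were examined. The rule names the called genes with the largest rises and falls among those whose arrays do not overlap: 10 and 10 for the LacZ comparison, 8 and 8 for each hairpin in arrays labelled tumor and 4 and 4 in arrays labelled spleen. For each tissue difference it names the 3 largest in each direction among called genes. It adds up to 4 called members of each list per comparison, the 5 targets in every group and up to 10 genes called the same way in the most comparisons labelled tumor. Predicted genes and clones without a known symbol were skipped. Of 138 pairs of a comparison and a gene named in it by size, 71 had other probe sets, 13 had at least 1 of opposite sign and 0 had a called one of opposite sign.

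The settings chosen beforehand were the mean of all probe sets, a filter keeping genes above the 40th percentile in at least 3 arrays, cyclic loess, fewer arrays in the fit, array weights, a replicate block (also by transduction), an absolute log2 difference of at least 1, an estimated list correlation, each other probe set of a target and leaving out each array in turn. Quantile normalization, with and without the filter, and fits without Ptpn2 array 1 labelled tumor or without the 3 arrays whose lowest value lay above -1.5 were added after seeing the data. The procedure was tested on simulated data. Changes of 0.5, 1, 2 and 4 on the log2 scale were put into 50 genes each. The Ppp2r2d comparison labelled tumor recovered 0, 5, 42 and 50 of them and made 9 false calls among the unchanged genes. The Ppp2r2d tissue difference recovered 0, 1, 19 and 46, with 6 false calls.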

Results

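RNA was measured on 36 arrays of mouse CD8 T cells, 12 groups of 3 arrays each. OT-I cells carry a T cell receptor for an ovalbumin peptide. They were transduced with a short hairpin RNA (shRNA) and transferred into mice bearing B16, a melanoma cell line. The hairpins targeted LacZ, a bacterial gene that serves as the control, or 1 of 5 mouse genes: Ppp2r2d, Egr2, Ptpn2, Arhgap5 and Alk. For each of the 6 transductions the labels give 3 arrays as spleen and 3 as tumor. The series asks about genes that govern how many T cells are present in tumors relative to spleens. Of each array 18193 genes were tested. Array medians lay between -0.48 and -0.23 on the deposited log2 scale, and the number of arrays limits the precision. Nothing in the labels says that the 3 arrays of a group come from separate animals, so each p measures the spread between arrays. Differences are log2, given with their SE where 1 is printed, and n = 3 arrays a group throughout.

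Pigment cell genes were high in the arrays labelled spleen and low in those labelled tumor. Dct, which encodes an enzyme of melanin synthesis, read 4.29 to 5.87 in the 18 arrays labelled spleen and -2.58 to -0.97 in the 18 labelled tumor. Mlana, a melanosome protein, read 4.19 to 5.94 against -3.21 to -1.17, and Tyrp1 4.61 to 6.18 against -2.94 to -1.01. Pdcd1, the inhibitory receptor PD-1 of stimulated T cells, read 6.13 to 7.06 against -1.77 to -0.02. The granzyme gene Gzmf read 2.52 to 7.0 against -3.40 to -0.94. T cell genes were high under both labels: Cd8a read 6.13 to 7.46 and 6.25 to 7.21. These levels oppose what the tissue labels lead one to look for, so the arrays are called "labelled spleen" and "labelled tumor" throughout, and every direction between tissues rests on those labels.

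**Figure D1:**
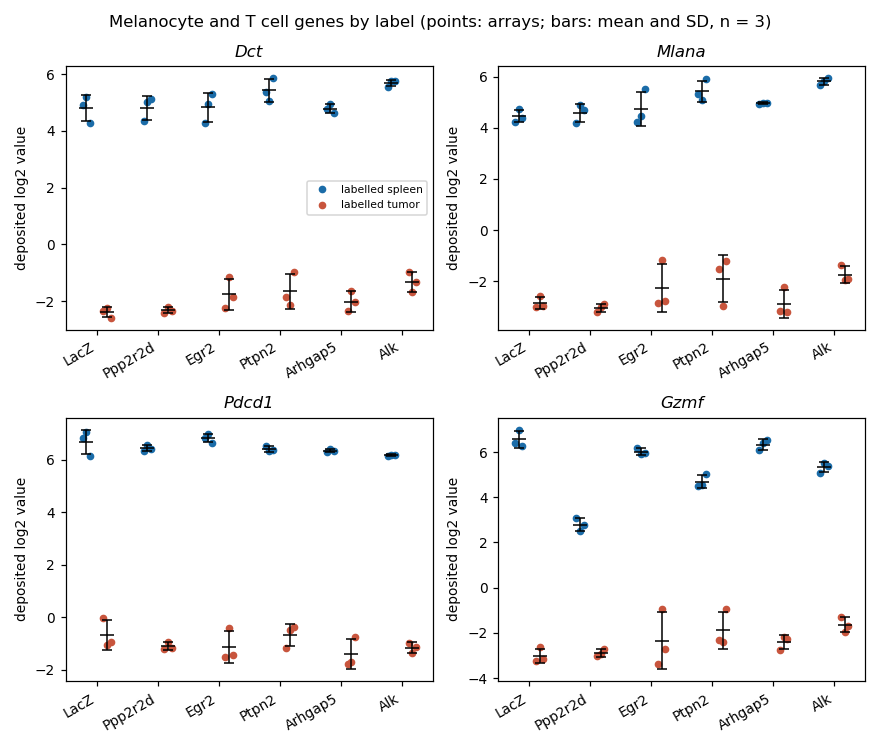
Deposited log2 values of Dct, Mlana, Pdcd1 and Gzmf (y axis) in the 6 transductions (x axis), with points for arrays and bars for mean and SD of 3. All 18 arrays labelled spleen lie above all 18 labelled tumor for each of these genes, for Dct at 4.29 or more against -0.97 or less.

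Some arrays stood apart from the rest. Ptpn2 array 1 labelled tumor correlated at most 0.891 with any other array, against 0.954 to 0.993 for the other 35. Its Gapdh probe sets differed by 2.94 between the 3' and 5' end of the transcript, a sign of RNA breakdown, against 0.25 to 1.39 elsewhere, and its T cell identity genes had a median of 4.25 against 5.65 to 7.21. The 3 LacZ arrays labelled spleen had best correlations of 0.954 to 0.971 and Gapdh values of 0.83 to 1.39. In the other 15 arrays labelled spleen these were 0.982 to 0.991 and 0.25 to 0.83. LacZ array 2 labelled spleen, Egr2 array 2 labelled tumor and Ptpn2 array 3 labelled tumor had the highest lowest values (-1.45 to -1.38, against -4.51 to -1.88). Differences of genes with a group mean near such values, Y-linked genes among them, are not exact in size or order.

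Each targeted gene was first compared with LacZ in the groups that received its hairpin. Ppp2r2d, a regulatory subunit of the phosphatase PP2A, fell in arrays labelled spleen from 4.99 ± 0.62 (SD) to 3.62 ± 0.29, a difference of -1.37 ± 0.42 (SE; limma adjusted p = 0.0286). Its other probe sets gave -1.17 and -0.96. In arrays labelled tumor the difference was -0.13 ± 0.42 (4.00 ± 0.15 against 4.13 ± 0.27; adjusted p = 0.902). Leaving out any of 5 of the 6 arrays labelled spleen ended the call (adjusted p = 0.0561 to 0.0939, differences -1.71 to -1.12). Without LacZ array 3 labelled tumor, the labelled tumor difference was 0.01.

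Egr2, a transcription factor induced by T cell receptor signals, differed by -1.19 ± 0.55 in arrays labelled spleen (3.97 ± 0.10 against 5.16 ± 0.66; limma adjusted p = 0.207). A second probe set gave -1.43 (adjusted p = 0.021 over all probe sets). In arrays labelled tumor the probe sets gave -0.09 and 0.09, and leaving out LacZ array 3, Egr2 array 1 or Egr2 array 3 turned the first to 0.27, 0.13 and 0.11. Ptpn2, a phosphatase that limits JAK-STAT and T cell receptor signals, differed by -0.79 ± 0.29 in arrays labelled spleen (4.38 ± 0.39 against 5.17 ± 0.48; adjusted p = 0.0727). It was called after cyclic loess (-0.78; adjusted p = 0.000268), after quantile normalization (-0.84; adjusted p = 4.32e-05) and without LacZ array 3 labelled spleen (-0.99; adjusted p = 0.0426). In arrays labelled tumor it was -0.38 ± 0.29 (4.96 ± 0.43 against 5.34 ± 0.28; adjusted p = 0.417).

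Arhgap5 was not lower in its labelled spleen group (0.45 ± 0.35, levels 0.02 ± 0.55 and -0.42 ± 0.28; limma adjusted p = 0.396). Of its other probe sets 1 gave 0.54 (adjusted p = 0.194 over all probe sets), and 2 turned it to -0.60 and -0.64 (adjusted p = 0.366 and 0.314). In arrays labelled tumor it differed by -0.47 ± 0.35 (adjusted p = 1). Alk, a receptor tyrosine kinase, read near the lower end of the arrays, with its mean at percentile 25.1 of all genes. It differed by -1.32 ± 0.48 in arrays labelled spleen (-2.24 ± 0.47 against -0.91 ± 0.93; adjusted p = 0.0828) and 1.13 ± 0.48 in arrays labelled tumor (adjusted p = 0.138). Without LacZ array 3 labelled spleen the first was -1.85 (adjusted p = 0.0235), and without LacZ array 2 labelled tumor the second was 1.69 (adjusted p = 0.0363). Alk was also lower with the Ptpn2 and Arhgap5 hairpins in arrays labelled spleen (-1.89 and -1.90; adjusted p = 0.0133 and 0.0132). With the Ppp2r2d and Egr2 hairpins it differed by -1.39 and -1.63 there (adjusted p = 0.0514 and 0.0524), so all 4 lay further below LacZ than its own group. Fitted with arrays labelled spleen alone, Egr2, Ptpn2 and Alk were also called in their own groups (adjusted p = 0.0152, 0.0341 and 0.0254), while with all 36 arrays only Ppp2r2d of the 5 targets was.

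**Figure D2:**
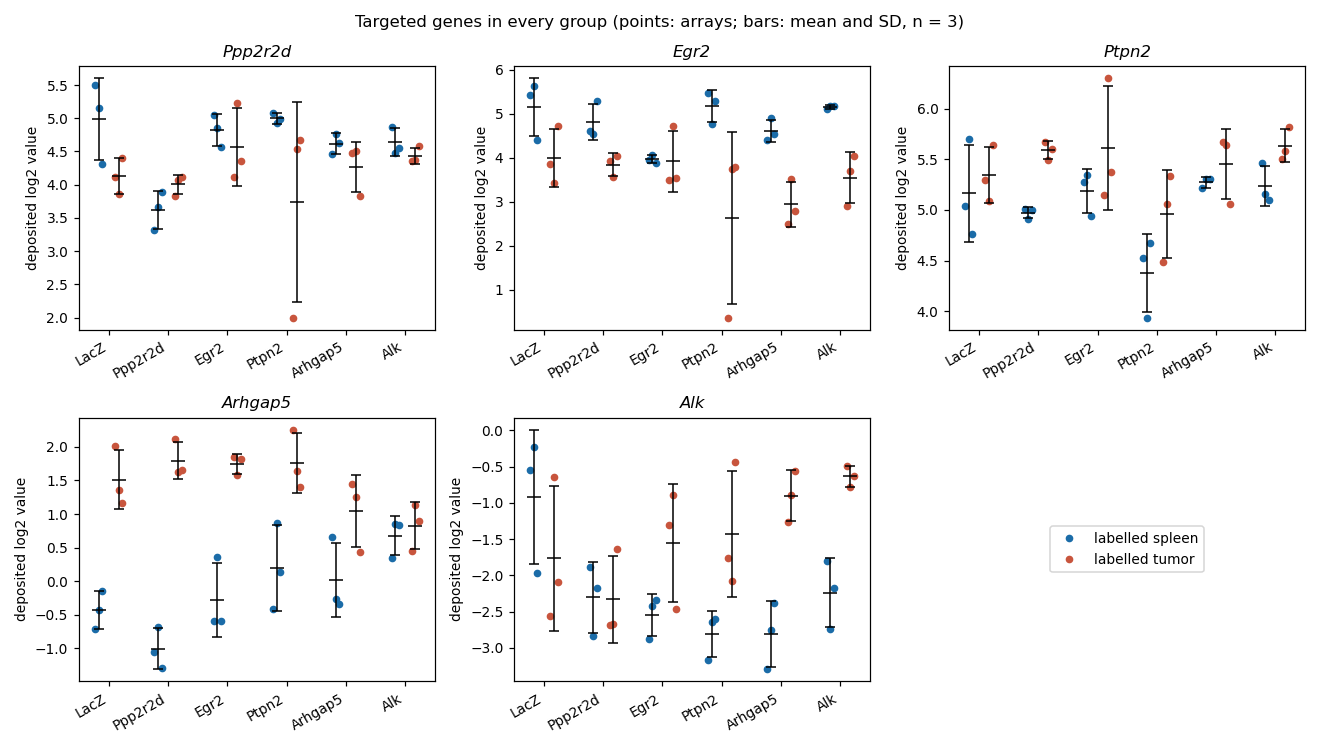
Deposited log2 values of the 5 targeted genes (y axis) in the 6 transductions (x axis), with points for arrays and bars for mean and SD of 3. Ppp2r2d in its own labelled spleen group averages 3.62 against 4.99 in LacZ, while Arhgap5 averages 0.02 against -0.42.

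Between the labels of the LacZ control, cytotoxic, inhibitory and pigment cell genes were lower in arrays labelled tumor, and 10 of 19 naive and memory genes were higher. Granzymes kill target cells, and Gzmf (-9.57), Gzme (-9.32), Gzmd (-8.95) and Gzmc (-8.58) fell. Serpinb9b fell by 8.13. Pdcd1 fell by 7.34 and the chemokine gene Ccl1 fell by 7.33. The melanin genes Tyrp1 (-7.71), Mlana (-7.32) and Dct (-7.19) fell. In LacZ arrays labelled tumor these 10 genes averaged -0.67 (Pdcd1) down to -3.75 (Gzmd), 8 of them under -2 and near the lowest values. The 10 largest falls had limma adjusted p of 1.2e-18 to 2.09e-14. Among the 10 largest rises were the receptor gene Treml2 (4.56 ± 0.31), the transcription factor gene Klf3 (4.52 ± 0.33) and Aqp9 (4.51 ± 0.34), a glycerol channel of memory T cells. The others were Pou6f1 (4.12), Tdrp (4.01), Nrarp (3.99, a Notch target), Lncpint (3.94), Gzmm (3.88), Tmem86b (3.85) and Slc16a5 (3.82). These rises had adjusted p of 6.54e-13 to 3.63e-07. Tmem86b was 0.90 with the mean of its probe sets (adjusted p = 0.0696).

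In all, 4589 genes changed between the labels, 1148 up and 3441 down in arrays labelled tumor. The median over all genes was -0.48 in deposited values and -0.06 after quantile normalization, so changes are best read relative to it. Quantile normalization gave 2300 up and 3266 down, and cyclic loess 2251 and 3548. With fewer arrays in the fit, only the 6 of LacZ, 1862 were called.

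T cell state lists moved apart. Of 19 measured inhibitory receptor and exhaustion genes 15 fell, 15 adjusted over the list alone (median -2.16; limma camera adjusted p = 2.34e-12, 0.0665 with an estimated correlation). They included Rgs16 (-6.30), Lag3 (-5.73) and Havcr2 (-5.57), and 1 more rose over the list alone. Of 23 cytotoxic genes 15 fell and 2 rose, the same counts over the list alone (median -1.85; adjusted p = 4.16e-09, 0.134 estimated). Of 19 cytokine and chemokine genes 13 fell and 1 rose, 14 and 1 over the list alone (median -1.64; adjusted p = 4.14e-06, 0.134 estimated), among them Il10 (-5.57) and Ccl9 (-6.28). Of 19 naive and memory genes 10 rose and 0 fell, 10 over the list alone (median 0.93; adjusted p = 5.36e-11, 0.0876 estimated). S1pr1 rose by 3.48, Klf2 by 2.15 and Il6ra by 3.31. Of 18 homing and residency genes 3 rose and 5 fell, 3 and 6 over the list alone (adjusted p = 0.908), with Cxcr6 at -3.89. Of 11 T cell identity genes 1 fell, Cd8a, and 0 over the list alone (median -0.21, camera direction up, adjusted p = 0.43). Cd8a differed by -0.63 (adjusted p = 0.0477) and by -0.06 after quantile normalization (adjusted p = 0.74). Its call ended without LacZ array 1 or 2 labelled spleen or any of the 3 labelled tumor (adjusted p up to 0.288, without labelled spleen array 2).

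Growth and metabolism genes were lower in arrays labelled tumor. Of 32 cell cycle genes 31 fell, and 32 over the list alone (median -2.85; limma camera adjusted p = 7.83e-26, 0.0665 with an estimated correlation). The mitotic genes Bub1, Aurkb and Kif11 read -4.32, -3.81 and -3.74. Of 20 glycolysis and hypoxia genes 19 fell, 19 over the list alone (median -1.56; adjusted p = 2.14e-10, 0.134 estimated), with Bnip3 at -3.62 and Tpi1 at -3.20. Of 13 cholesterol synthesis genes 12 fell, 12 over the list alone (median -1.45; adjusted p = 6.75e-06, 0.276 estimated), with Idi1 at -2.92 and Cyp51 at -2.52. Of 21 oxidative phosphorylation genes 11 fell, and 15 over the list alone (median -0.80, after quantile normalization -0.25; adjusted p = 0.0053, 0.667 estimated), with Cycs at -1.55. Of 18 stress response genes 9 fell and 1 rose, 10 and 2 over the list alone (adjusted p = 0.0128, 0.553 estimated), with Asns at -3.32.

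Signalling lists were mixed. Of 21 immediate early genes, switched on within minutes of receptor signals, 6 rose and 2 fell, the same over the list alone (median 0.60; limma camera adjusted p = 7.58e-05, 0.472 with an estimated correlation). Ier2 read 2.22, Fosb 2.08 and Ier3 -2.92. Of 26 interferon response genes 9 rose and 4 fell, 10 and 5 over the list alone (median 0.49; adjusted p = 0.000251, 0.502 estimated), with Ifit1 at 1.67 and Irf1 at 1.48. Of 22 JAK-STAT targets 4 rose and 7 fell, 4 and 9 over the list alone (adjusted p = 0.998). Of 19 anergy and receptor brake genes 2 rose and 5 fell, 3 and 5 over the list alone (adjusted p = 0.955). Of 16 apoptosis genes 1 rose and 3 fell, the same over the list alone (median -0.11, camera direction up, adjusted p = 0.417). Of 11 heat shock genes 4 fell, and of 17 PP2A subunits 4 fell, the same over the list alone (adjusted p = 0.79 and 0.908).

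Pigment cell and macrophage markers were lower in arrays labelled tumor. Of 13 melanocyte genes 11 fell, 11 over the list alone (median -3.53; limma camera adjusted p = 3.25e-14, 0.0569 with an estimated correlation), with Ptgds at -6.35. Of 20 myeloid genes 16 fell, and 17 over the list alone (median -2.21; adjusted p = 1.53e-10, 0.0665 estimated). C1qb, a complement gene of macrophages, read -6.05, Lyz2 -5.94 and Csf1r -4.31. Of 11 dendritic cell and MHC class II genes 5 fell, 5 over the list alone (adjusted p = 0.0288, 0.405 estimated), with H2-Aa at -5.24 and Cd74 at -3.74. Of 9 erythroid genes 2 rose, 2 over the list alone (median 0.66; adjusted p = 0.0153, adjusted p = 0.0567 after quantile normalization and adjusted p = 0.509 estimated), with Car1 at 3.74. Of 14 B cell genes 2 rose (Ighm 1.17, Cd79b 1.35) and 1 fell, the same over the list alone (median -0.22, camera direction up, adjusted p = 0.229). Of 11 neutrophil genes 1 fell and 0 over the list alone, and of 12 stroma and endothelium genes 1 rose and 3 fell, the same over the list alone (adjusted p = 0.76 and 0.663). Of 9 CD4 and NK cell genes 1 rose and 2 fell, 1 and 3 over the list alone (adjusted p = 0.43).

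With the Ppp2r2d hairpin in arrays labelled tumor, more genes were called up than down, and Ctse rose most. Ctse, an aspartic protease gene, rose by 4.37 ± 0.43, and the receptor phosphatase gene Ptprv by 2.71 ± 0.28. Ahr rose by 2.50 ± 0.38, and Morrbid, a long noncoding RNA, by 2.37 ± 0.33. The others of the 8 largest rises were Prss30 (3.00), Mical2 (2.61), Mmp10 (2.56) and Ramp3 (2.44), and all 8 had limma adjusted p of 2.41e-07 to 0.00401. The largest falls were Plxna2 (-2.37 ± 0.58), Cyp2s1 (-2.20), Cacna2d1 (-2.01), Insm2 (-1.94), Ifitm1 (-1.94), Ppp2r2c (-1.84, a relative of the target), C3ar1 (-1.83) and Styk1 (-1.81), with adjusted p of 0.000423 to 0.0458. Ppp2r2c and C3ar1 were not called after quantile normalization (adjusted p = 0.0932 and 0.079). With the mean of their probe sets 5 falls were not called: Plxna2 (-1.0), Cacna2d1 (-0.82), Insm2 (-0.73), Ppp2r2c (-0.86) and C3ar1 (-0.87).

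Among fixed lists, of 13 cholesterol synthesis genes 1 rose, Cyp51 (1.26), and 6 over the list alone (median 0.64; limma camera adjusted p = 7.79e-05, 0.913 with an estimated correlation). Of 26 interferon response genes 1 rose, Oas2 (1.61 ± 0.29), and 2 over the list alone (median 0.31, 0.01 after quantile normalization; adjusted p = 0.00922, then 0.823, and 0.913 estimated). Among 20 myeloid genes 1 fell, Tyrobp (-1.40), and 1 over the list alone (median -0.46; adjusted p = 0.00795, 0.16 after quantile normalization, and 0.913 estimated). Of 11 neutrophil and 12 stroma genes 0 were called by limma, 0 over the list alone, while camera gave adjusted p = 0.00795 and 0.037 (both down, 0.256 and 0.296 after quantile normalization, and 0.913 estimated). Of 9 CD4 and NK cell genes 1 fell, 1 over the list alone (median -0.36; adjusted p = 0.0392, 0.0889 after quantile normalization, and 0.913 estimated). The inhibitory receptor gene Lag3 rose by 1.47 ± 0.28 (adjusted p = 0.00488), 1 of 19 in its list. Of 13 melanocyte genes 2 rose, 2 over the list alone: Trpm1 (1.86, but 0.44 and adjusted p = 0.535 with the mean of its probe sets) and Gpnmb (1.55, and 0.00 with that mean).

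Here 181 genes changed, 157 up and 24 down. Quantile normalization gave 257 up and 135 down, cyclic loess 264 and 175, and fewer arrays 36. The count was 814 without LacZ array 1, 54 without LacZ array 2, and 70, 81 and 58 without Ppp2r2d array 1, 2 and 3. Single arrays ended the calls of Plxna2 and Cyp51 (5 of the 6 arrays each; adjusted p up to 0.531 and 0.223, both without LacZ array 2), Tyrobp (5 of 6; 0.174 without Ppp2r2d array 3), Cacna2d1, Ppp2r2c, C3ar1 and Gpnmb (4 of 6 each; 0.268, 0.561, 0.38 and 0.237 without LacZ array 2). The same held for Lag3 without LacZ array 2 (0.0877), Insm2 without LacZ array 2 (0.0632) or Ppp2r2d array 1, and Ifitm1 without Ppp2r2d array 1 (0.0924) or 3.

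With the Egr2 hairpin in arrays labelled tumor only 5 genes changed, 2 up and 3 down. Ctse rose by 4.08 ± 0.43 and Ptprv by 1.96 ± 0.28 (limma adjusted p = 1.71e-06 and 0.000787). Psrc1, a mitotic spindle gene, fell by 2.28, the aminopeptidase gene Rnpep by 2.03 and Cdkn1a, the cell cycle inhibitor p21, by 1.48 (adjusted p = 0.0144, 0.00103 and 0.0199). With the mean of probe sets neither Psrc1 (-1.32; adjusted p = 0.393) nor Cdkn1a (-1.33; adjusted p = 0.138) was called.

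No cell cycle or interferon gene was called over all genes, and camera placed both lists below the all-gene median of 0.29 at the preset correlation only. Of 32 cell cycle genes 0 changed, 0 over the list alone (median -0.10; limma camera down, adjusted p = 8.71e-11, 0.657 with an estimated correlation). Of 26 interferon genes 0 changed, with 1 lower over the list alone (median -0.02; adjusted p = 6.36e-07, 0.657 estimated), and of 19 cytokine genes 0, with 2 lower over the list alone (adjusted p = 6.36e-07, 0.58 estimated). Of 11 heat shock genes 0 changed (adjusted p = 4.15e-05, 0.586 estimated). The immediate early, JAK-STAT and glycolysis lists had medians of 0.04, 0.08 and 0.00 while camera put them down (adjusted p = 0.00174, 0.003 and 0.00174, 0.788 estimated for each). Of 9 erythroid genes 0 changed, and camera placed the list above the other genes at the preset correlation only (median 0.64; adjusted p = 0.0191, 0.788 estimated).

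In total 973 genes had an unadjusted p under 0.05. Quantile normalization moved the all-gene median from 0.29 to 0.01 and gave 4 up and 7 down, loess 5 and 13, and fewer arrays 2. Without Egr2 array 1 the count was 3. Psrc1 lost its call without LacZ array 1, Egr2 array 1 or Egr2 array 3 (adjusted p up to 0.346), and Cdkn1a without LacZ array 2, LacZ array 3 or Egr2 array 1 (up to 0.356), each highest without Egr2 array 1.

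With the Ptpn2 hairpin in arrays labelled tumor, Y-linked genes and some cytotoxic and homing genes rose. Gzmk rose by 3.78 ± 0.31 and Gzmb by 2.01 ± 0.31 (limma adjusted p = 1.35e-09 and 0.000256). The effector cell receptor genes Klrg1 and Cx3cr1 rose by 2.48 and 2.72. The Y-linked genes Eif2s3y, Kdm5d and Uty rose by 8.48, 5.83 and 3.37, Orly by 5.69 and Astx3 by 3.57. Their LacZ means were -2.82, -3.61, -3.31, -1.30 and -3.05, so these sizes are not exact. Xist, the RNA that silences an X chromosome in female cells, fell by 5.20 ± 0.55. A donor sex difference is not separable from the Ptpn2 and Arhgap5 hairpins. Ctse rose by 4.35 ± 0.43, Ptprv by 2.25 ± 0.28 and Esm1 by 3.61. The 8 largest rises had adjusted p of 2.48e-15 to 0.000192. After Xist the largest falls were Akr1c13 (-2.45 ± 0.61), the Fc receptor gene Fcgr2b (-2.31), Myl10 (-2.03), the cytokine gene Csf2 (-1.91), the lipase inhibitor gene G0s2 (-1.88), Styk1 (-1.78) and Fhit (-1.75), with adjusted p of 3.26e-07 to 0.0484.

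Of 23 cytotoxic genes 4 rose, Gzmk, Klrg1, Gzmb and Klrk1 (1.56), and 9 over the list alone (median 0.82; limma camera adjusted p = 5.59e-05, 0.85 with an estimated correlation). Of 19 inhibitory receptor genes 3 rose, Lag3 (2.33 ± 0.28), Rgs16 (1.77) and Havcr2 (1.42), with 4 up and 2 down over the list alone (adjusted p = 0.405). Of 18 homing genes 5 rose, with 6 up and 1 down over the list alone (median 0.43; adjusted p = 0.0104, 0.85 estimated), among them Cxcr6 (2.41), Itga1 (2.10) and Ccr2 (2.08). Of 32 cell cycle genes 0 changed and 5 rose over the list alone (median 0.40; adjusted p = 0.0202, 0.85 estimated).

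Camera with the preset correlation placed several lists below the other genes, whose median was above 0. Among 26 interferon genes 1 fell, Ifit1 (-1.73 ± 0.35), and 4 over the list alone (median -0.02, 0.03 after quantile normalization; limma camera adjusted p = 0.00079, then 0.152, and 0.85 with an estimated correlation). Of 21 immediate early genes 0 changed and 4 fell over the list alone (median -0.45; adjusted p = 2e-06, 0.85 estimated). Of 19 cytokine genes 1 fell and 5 over the list alone (median 0.06, camera direction down, adjusted p = 0.00917, 0.85 estimated). Heat shock, oxidative phosphorylation, glycolysis and apoptosis lists had 0 members called, and camera put them down (adjusted p = 0.00686, 0.0104, 0.0143 and 0.0202, 0.85 estimated for each). Glycolysis and apoptosis lost this after quantile normalization (adjusted p = 0.195 and 0.42).

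Here 139 genes changed, 117 up and 22 down. The all-gene median moved with quantile normalization from 0.24 to 0.02 and gave 339 up and 189 down, loess 298 and 133, and fewer arrays 28. The count was 366 without LacZ array 2 and 49 without LacZ array 3. It was 57 without Ptpn2 array 1, the array with the low correlations, 4003 without Ptpn2 array 2 and 383 without Ptpn2 array 3. Akr1c13, Fcgr2b and Csf2 lost their calls without Ptpn2 array 1 (adjusted p = 0.494, 0.141 and 0.0829) and without LacZ array 3, and Akr1c13 without LacZ array 1. Fhit (0.0726), Havcr2 (0.0741) and Ifit1 (0.0569) lost theirs without LacZ array 3, and Havcr2 also without LacZ array 2.

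With the Arhgap5 hairpin in arrays labelled tumor, Y-linked genes rose and 8 of 32 cell cycle genes fell. Nusap1, Kif11, Ccna2 and Bub1, all needed for mitosis, fell by 2.31, 2.25, 2.24 and 2.22. The antibody genes Igk (-4.72 ± 1.07), Igkv8-30 (-4.26 ± 0.96) and Jchain (-4.19 ± 0.81) fell, and so did the granzyme gene Gzma (-2.69 ± 0.40). Xist fell by 5.96, Psrc1 by 2.64, the replication gene Mcm10 by 2.48 and the interferon-induced gene Ifitm1 by 2.41. These 8 largest falls had limma adjusted p of 2.16e-08 to 0.0393. Eif2s3y, Kdm5d, Orly and Uty rose by 8.44, 6.07, 5.69 and 4.92, Ctse by 3.89, Astx3 by 3.38, the NK receptor gene Klra5 by 2.46 and Cphx3 by 1.88, with adjusted p of 2.78e-15 to 0.0484. Ptprv rose by 1.62 and Rnpep fell by 2.21 (adjusted p = 0.00188 and 7.44e-05).

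Of 32 cell cycle genes 8 fell, and 16 over the list alone (median -0.88; limma camera adjusted p = 1.91e-34, 0.0737 with an estimated correlation). Of 26 interferon genes 1 fell, Ifit1 (-1.97 ± 0.35), and 2 over the list alone (median -0.29; adjusted p = 2.58e-08, 0.602 estimated). Of 19 cytokine genes 1 fell, Lif (-1.99), and 5 over the list alone (adjusted p = 0.000166, 0.602 estimated). Of 19 inhibitory receptor genes 1 fell, Havcr2 (-1.56), and 1 over the list alone (adjusted p = 0.00598, 0.249 after quantile normalization, and 0.671 estimated). With 0 members called, camera put down the naive and memory (adjusted p = 0.000772), erythroid (0.000525), immediate early (0.00197), heat shock (0.00579) and MHC class II lists (0.0275, and 0.0714 after quantile normalization). With an estimated correlation these gave adjusted p = 0.614 to 0.808. With the mean of their probe sets Bub1 (-0.89; adjusted p = 0.524), Nusap1 (-1.37; 0.0863), Psrc1 (-1.16; 0.179), Lif (-1.09; 0.15), Igk (-1.46; 0.608) and Cphx3 (0.99; 0.449) were not called.

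Here 67 genes changed, 13 up and 54 down. Quantile normalization gave 52 up and 117 down, loess 40 and 130, and fewer arrays 20. The count was 28, 194 and 36 without LacZ array 1, 2 and 3, and 27 and 38 without Arhgap5 array 1 and 3. Igk and Igkv8-30 lost their calls without any of 5 of the 6 arrays (adjusted p up to 0.383 and 0.333, without Arhgap5 array 3), and Cphx3 likewise (up to 0.473, without LacZ array 3). Havcr2 lost it without LacZ array 1 or 3 or Arhgap5 array 2 or 3 (up to 0.189), and Jchain without LacZ array 3 (0.0675) or Arhgap5 array 1 or 3. Nusap1 and Ccna2 lost it without LacZ array 1 or Arhgap5 array 1 (up to 0.0953 and 0.102), and Lif without Arhgap5 array 1 (0.0581).

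With the Alk hairpin in arrays labelled tumor 1 gene changed: Styk1, a kinase-like gene, fell by 1.94 ± 0.30 (limma adjusted p = 0.00514). It was not called without LacZ array 3 (adjusted p = 0.127) or Alk array 1, which left a count of 0. In all, 4663 genes had an unadjusted p under 0.05. The count was 4 without LacZ array 1 and 1691 without LacZ array 2. After quantile normalization the all-gene median moved from 0.33 to -0.01 and gave 30 up and 37 down, and loess 17 and 37, while limma with fewer arrays in the fit called 0 (3522 at unadjusted p under 0.05).

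Camera placed cell cycle and interferon genes below the other genes here too, at the preset correlation only, 0 called. Of 32 cell cycle genes 9 fell over the list alone (median -0.41; limma camera adjusted p = 1.65e-16, 0.372 with an estimated correlation). Among 26 interferon genes 2 fell over the list alone (median -0.25; adjusted p = 1.31e-12, 0.372 estimated), and of 19 cytokine genes 3 (adjusted p = 1.94e-05, 0.372 estimated). JAK-STAT targets and glycolysis genes had medians of 0.16 and 0.09 while camera put them down (adjusted p = 0.00281 and 0.0132, 0.839 estimated). The immediate early list had a median of 0.00 and heat shock -0.09 (adjusted p = 0.00281 for each, adjusted p = 0.839 and 0.781 estimated).

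In arrays labelled spleen the Ppp2r2d hairpin went with higher Ctse and a B cell list call that an estimated correlation ended. The mean of that list was higher in LacZ arrays labelled spleen (-0.27) than in all 5 hairpin groups (-1.48 to -1.05), and these LacZ arrays stood apart in correlation and Gapdh values. Ctse rose by 6.83 ± 0.43, the NK receptor gene Klrb1a by 4.69 ± 0.57, the growth factor adaptor gene Grb10 by 3.97 ± 0.43 and Igfbp2 by 3.89 ± 0.37 (limma adjusted p = 3.13e-12 to 1.79e-06). The largest falls were Lad1 (-4.31 ± 0.53), Jchain (-4.24 ± 0.81), Gzmf (-3.76 ± 0.40) and Kalrn (-3.44 ± 0.68), with adjusted p of 2.32e-07 to 0.00111. Of 23 cytotoxic genes 8 fell and 2 rose, the same over the list alone (adjusted p = 0.131), with Gzmg at -2.46, Gzmd at -2.06 and Gzmm at 3.09. Il10 read -3.40, Havcr2 -1.78 and Cish -2.13. Of 19 cytokine genes 4 fell and 2 rose, 6 and 2 over the list alone (adjusted p = 0.352, but 0.0107 after quantile normalization). Among 14 B cell genes 6 fell, and 7 over the list alone (median -1.09; limma camera adjusted p = 0.0161, 0.974 with an estimated correlation), with Ebf1 at -2.92 and Cd22 at -2.07. Of 20 glycolysis genes 2 fell, and 6 over the list alone (median -0.52; adjusted p = 0.0383, 0.974 estimated). Of 17 PP2A subunits 1 rose, Ppp2r3a (2.20 ± 0.45), and 1 fell, the target.

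Here 2334 genes changed, 1118 up and 1216 down. Quantile normalization moved the all-gene median from -0.24 to 0.00, kept 1305 of these and gave 1298 up and 854 down. Loess gave 1441 and 1012, fewer arrays 4479. The count was 826 and 1064 without Ppp2r2d array 2 and 3. Gzmd lost its call without LacZ array 2 (adjusted p = 0.0555) or Ppp2r2d array 2, and Ebf1 without Ppp2r2d array 2 (0.0767) or 3.

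The Egr2 hairpin in arrays labelled spleen went with higher Ctse, and with myeloid and B cell list calls that an estimated correlation ended. Ctse rose by 6.54 ± 0.43, Khdc1a by 2.40, Gzmm by 2.14 and Sult2b1 by 2.13 (limma adjusted p = 1.03e-11 to 0.00892). Lad1 fell by 4.55 ± 0.53, Dmp1 by 3.50 ± 0.96, Chrdl1 by 3.06 and Hoxd10 by 3.01 (adjusted p = 1.14e-05 to 0.0398). Of 20 myeloid genes 4 rose, with 6 up and 1 down over the list alone (median 0.80; limma camera adjusted p = 7.88e-06, 0.922 with an estimated correlation), among them C1qa (1.44), Cd68 (1.15) and Fcgr3 (1.09). Of 14 B cell genes 2 fell, and 6 over the list alone (median -0.90; adjusted p = 0.0371, 0.0659 after quantile normalization, and 0.922 estimated). Of 26 interferon genes 0 were called (median 0.19; adjusted p = 0.025, 0.248 after quantile normalization, and 0.922 estimated). Klrg1 rose by 1.32, and Il10 fell by 1.73. C1qa, Fcgr3 and Dmp1 were not called after quantile normalization (adjusted p = 0.153, 0.0833 and 0.0556), nor Dmp1 and Chrdl1 with the mean of probe sets (-1.68 and -1.44; adjusted p = 0.0776 and 0.0766).

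In this comparison 588 genes changed, 290 up and 298 down. The all-gene median moved from -0.18 to -0.01 with quantile normalization, which kept 289 of these and gave 426 up and 216 down. Loess gave 483 and 249, fewer arrays 2169. The count was 345 without LacZ array 2 and 90, 273 and 208 without Egr2 array 1, 2 and 3. Without Egr2 array 1 Khdc1a, Chrdl1, Klrg1, Dmp1, Hoxd10, Il10 and Cd68 were not called (adjusted p = 0.0728, 0.0525, 0.113, 0.124, 0.0909, 0.13 and 0.108). The last 4 of these, C1qa (up to 0.142, without LacZ array 2) and Fcgr3 (up to 0.0772, without Egr2 array 2) were lost without any of 4 or 5 of the 6 arrays.

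The Ptpn2 hairpin in arrays labelled spleen went with higher Y-linked genes and 8 of 26 interferon genes. Over the list alone 13 rose (median 0.86; limma camera adjusted p = 2.04e-10, 0.582 with an estimated correlation). They included Irf7 (1.34 ± 0.28), Oasl2 (1.25) and Ifit1 (1.10). The list mean here was 3.01 in LacZ arrays, which stood apart, and 3.23 (Egr2) to 3.78 (Ptpn2) with the hairpins. Eif2s3y, Kdm5d and Uty rose by 7.98, 5.69 and 4.11 and Ctse by 6.70 ± 0.43 (adjusted p = 1.42e-14 to 1.35e-05). Lad1 fell by 5.17 ± 0.53, Ntrk3 by 3.97, Arhgef15 by 3.83 and Hoxc8 by 3.74 (adjusted p = 3.23e-07 to 0.00653). Of 23 cytotoxic genes 2 rose and 5 fell, 3 and 5 over the list alone (adjusted p = 0.58), with Gzmk at 2.10, Gzmg at -3.02, Gzme at -2.56 and Gzmd at -2.52. Of 13 melanocyte genes 2 rose, Ptgds (1.37) and Pmel (1.13), 2 over the list alone (median 0.79; adjusted p = 0.00017, 0.582 estimated). Among 20 myeloid genes 3 rose and 1 fell, 7 and 1 over the list alone (median 0.73; adjusted p = 0.000208, 0.582 estimated), with Cd68 at 1.09. Among 14 B cell genes 4 fell, 4 over the list alone (adjusted p = 0.00202, 0.582 estimated). Ccr2 rose by 1.5 and Csf2 fell by 1.5.

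In this group 1743 genes changed, 614 up and 1129 down. Dim genes held 1206 of these calls. Ntrk3 averaged -3.12 with the hairpin, near the lowest values, against 0.85 in LacZ. After quantile normalization 587 genes were up and 462 down, 623 of the 1743 were kept, and the all-gene median moved from -0.15 to -0.01. Loess gave 690 and 636, fewer arrays 3852. The count was 889 without LacZ array 2 and 476, 1027 and 763 without Ptpn2 array 1, 2 and 3. Oasl2, Ifit1 and Cd68 were not called after quantile normalization (adjusted p = 0.0852, 0.267 and 0.0596), nor Pmel and Ptgds after loess (0.0602 and 0.17), nor Ntrk3 with the mean of its probe sets (-0.83; 0.0784). Pmel lost its call without any of 5 arrays (up to 0.154, without LacZ array 3), and Oasl2, Ifit1 and Ptgds without any of 4 (up to 0.129 without Ptpn2 array 1, and 0.14 and 0.138 without Ptpn2 array 3). Csf2 lost it without LacZ array 2 (0.0634) or Ptpn2 array 2, and Cd68 without LacZ array 3 (0.0655) or Ptpn2 array 1.

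The Arhgap5 hairpin in arrays labelled spleen went with higher Y-linked genes and Ctse, and its list calls ended with an estimated correlation. Eif2s3y, Kdm5d and Uty rose by 8.01, 5.74 and 4.45 and Ctse by 6.06 ± 0.43 (limma adjusted p = 1.28e-14 to 2.08e-06). Jchain fell by 4.20 ± 0.81, Lad1 by 4.08 ± 0.53, Chrdl1 fell by 3.73 and Trat1, an adaptor of the T cell receptor, by 3.69 ± 0.42 (adjusted p = 1.96e-06 to 0.00211). Of 23 cytotoxic genes 2 rose and 3 fell, the same over the list alone (adjusted p = 0.589), with Gzmm at 2.92 and Gzma at -2.75. Il10 fell by 2.78, S1pr1 by 2.19, and Csf2 rose by 1.83. Of 20 myeloid genes 5 rose, 5 over the list alone (median 0.78; limma camera adjusted p = 2.66e-06, 0.918 estimated), with Apoe at 1.58, C1qa at 1.37 and Fcgr3 at 1.36. Of 14 B cell genes 4 fell, and 6 over the list alone (adjusted p = 0.024, 0.994 estimated). Of 26 interferon genes 1 rose and 0 over the list alone (median 0.27; adjusted p = 0.00268, 0.0856 after quantile normalization, and 0.994 estimated).

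There 1617 genes changed, 551 up and 1066 down. Quantile normalization moved the all-gene median from -0.22 to 0.00, kept 734 of these and gave 833 up and 606 down. Loess gave 984 and 752, fewer arrays 4131. The count was 861 without LacZ array 2 and 812, 639 and 518 without Arhgap5 array 1, 2 and 3. Without Arhgap5 array 1 Apoe and C1qa were not called (adjusted p = 0.0857 and 0.171), C1qa also not without LacZ array 2, Arhgap5 array 3 or after quantile normalization (0.124).

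The Alk hairpin in arrays labelled spleen went with a broad rise of macrophage genes. Among 20 myeloid genes 15 rose, and 17 over the list alone (median 1.86; limma camera adjusted p = 2.17e-23, 0.00618 with an estimated correlation). Of the 97 list calls in the 16 comparisons this alone held with an estimated correlation. Apoe rose by 3.76 ± 0.38, C1qa by 2.64, Cd68 by 2.38 and Ms4a7 by 2.41. The matrix protease genes Mmp13 and Mmp12 rose by 4.44 ± 0.64 and 4.19 ± 0.50, the platelet and macrophage chemokine gene Pf4 by 4.08 ± 0.44 and the arginase gene Arg1 by 3.97 ± 0.35 (adjusted p = 1.56e-08 to 0.000102). Of 13 melanocyte genes 9 rose, and 11 over the list alone (median 1.26; adjusted p = 3.6e-10, 0.106 estimated), with Tyr at 1.95, Ptgds at 1.71 and Slc45a2 at 1.51. Among 26 interferon genes 3 rose, and 5 over the list alone (median 0.36; adjusted p = 0.00114, 0.116 after quantile normalization, and 0.992 estimated). Il10 fell by 2.56 and Gzmm rose by 1.79. Sparc, a stroma gene, rose by 1.98 and Mmp8, of neutrophils, by 3.11. The largest falls were Chrdl1 (-3.42 ± 0.63), AY702103 (-2.96 ± 0.94), Jchain (-2.94 ± 0.81) and Ccdc83 (-2.87 ± 0.60), with adjusted p of 0.00171 to 0.0492.

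In the Alk group 1347 genes changed, 661 up and 686 down. The all-gene median moved from -0.21 to -0.03 with quantile normalization, which kept 731 of these and gave 892 up and 449 down. Loess gave 1098 and 500, fewer arrays 3444. The count was 729 without LacZ array 2 and 500, 753 and 401 without Alk array 1, 2 and 3. AY702103 was not called after quantile normalization (adjusted p = 0.171) or without any of 5 arrays (up to 0.281, without LacZ array 3), nor Jchain without any of 4 (up to 0.14, without Alk array 3). Without Alk array 3 Tyr, Slc45a2 and Sparc were not called (0.0784, 0.0702 and 0.0628), Tyr also not without Alk array 1, Slc45a2 without LacZ array 3, and Ms4a7 not with the mean of its probe sets (0.55; 0.436).

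Whether a hairpin's effect differed between the labels was tested as a tissue difference, the effect in arrays labelled tumor minus that in arrays labelled spleen. For Ppp2r2d, Dtx1 differed by 4.11 ± 0.67 (0.70 in arrays labelled tumor, -3.41 in those labelled spleen). In arrays labelled tumor Gzmf (-2.88 against -3.01) and Klrb1a (-3.0 against -2.95) read near the lowest values, so for these only the change in arrays labelled spleen was readable. Gzmf differed by 3.89 ± 0.56 (0.13 and -3.76) and Cphx3 by 3.83 ± 0.63 (1.57 and -2.26). Grb10 differed by -5.28 ± 0.61 (-1.31 and 3.97), Klrb1a by -4.74 ± 0.81 (-0.05 and 4.69) and Igfbp2 by -4.58 ± 0.53 (-0.68 and 3.89), and all 6 had limma adjusted p of 8.22e-06 to 0.0016. Grb10 gave -1.75 with the mean of its probe sets (adjusted p = 0.0941). The integrin gene Itgae differed by 2.81, the STAT5 target Cish by 2.70, Il10 by 2.98, Cd22 by 2.58 and Gzmm by -2.69. Of 22 JAK-STAT targets 1 was higher, 1 over the list alone (median 0.56; limma camera adjusted p = 0.00246, 0.792 with an estimated correlation). The stress and B cell lists were up (adjusted p = 0.0111 for each, 0.0378 and 0.0954 after quantile normalization, and 0.792 estimated). Glycolysis was up (adjusted p = 0.000484) and myeloid and stroma genes down (1.02e-05 and 0.0208), none of them called after quantile normalization (0.474, 0.357 and 0.357; adjusted p = 0.792 estimated).

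The Ppp2r2d tissue difference held for 143 genes, 56 up and 87 down. After quantile normalization the all-gene median moved from 0.33 to 0.03 and gave 152 up and 213 down, loess 157 and 310, and fewer arrays 63. The count was 95 and 217 without LacZ array 1 and 3 labelled spleen, 87, 76 and 82 without Ppp2r2d array 1, 2 and 3 labelled spleen, and 94, 76 and 75 without those labelled tumor. Il10 lost its call without any of 6 of the 12 arrays (adjusted p up to 0.0745, without Ppp2r2d array 2 labelled tumor).

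For Egr2 limma called 0 genes with a tissue difference, while 3370 had an unadjusted p under 0.05. The all-gene median was 0.43, and 0.02 after quantile normalization, which gave 3 up and 12 down. Without LacZ array 1 or 3 labelled spleen 38 and 87 genes were called, without LacZ array 2 labelled tumor 590 and without Egr2 array 3 labelled tumor 26. Camera placed interferon and myeloid genes below it (medians -0.25 and -0.45; limma camera adjusted p = 7.17e-06 for each, 0.991 with an estimated correlation). Camera placed B cell genes above the all-gene median at the preset correlation only, 0 called and 3 over the list alone (median 1.29; adjusted p = 0.0226, 0.991 estimated). Cell cycle genes had a median of 0.07 while camera put them down (adjusted p = 0.0171, 0.187 after quantile normalization, and 0.991 estimated).

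For Ptpn2, 8 of 26 interferon genes were lower in arrays labelled tumor than spleen, each relative to LacZ. Over the list alone it was 9 (median -0.76; limma camera adjusted p = 2.03e-10, 0.909 with an estimated correlation). From arrays labelled spleen to tumor the list mean rose from 3.01 to 3.33 in LacZ. It fell from 3.78 to 3.02 with Ptpn2, and every tissue difference shares LacZ. Gbp2 and Iigp1, induced by interferon gamma, differed by -3.96 ± 0.92 (-2.20 and 1.76) and -3.01 ± 0.44 (-0.35 and 2.65). Gpr137b differed by -3.06 ± 0.51. Ifit1 differed by -2.84 and Oasl1 by -2.44. Of 23 cytotoxic genes 11 were higher and 1 lower, 12 and 1 over the list alone (median 1.08; adjusted p = 0.00467, 0.909 estimated), with Gzmg at 3.55, Gzme at 3.45 and Gzmf at 3.01 (2.75, 2.45 and 2.08 after quantile normalization). In LacZ arrays labelled tumor these 3 averaged -2.89, -3.42 and -3.01, near the lowest values. Cx3cr1 differed by 1.59 and Lag3 by 1.36. The largest rises were Ntrk3 (4.99 ± 1.22), Ugt2b36 (4.96 ± 0.94) and Zfp957 (4.93 ± 1.15), whose means in Ptpn2 arrays labelled spleen, -3.12, -3.02 and -1.94, lay near the lowest values. The 6 largest had adjusted p of 0.00114 to 0.0146. Among 14 B cell genes 6 were higher, and 9 over the list alone (adjusted p = 0.011, 0.909 estimated). Of 11 neutrophil genes 4 were higher, and 6 over the list alone (adjusted p = 0.0416, 0.824 after quantile normalization, and 0.909 estimated). Immediate early and myeloid lists were down (adjusted p = 0.00467 and 0.0416, 0.909 estimated).

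The Ptpn2 count was 3151, 2747 up and 404 down. Quantile normalization moved the all-gene median from 0.29 to 0.03 and gave 212 up and 192 down, with 247 genes called both ways, and loess gave 196 and 104. With only the 12 arrays of Ptpn2 and LacZ in the fit limma called 0 genes, while 3936 had an unadjusted p under 0.05, so every call here ended. The count was 4761 and 555 without LacZ array 1 and 2 labelled spleen, 827, 1691 and 1841 without Ptpn2 array 1, 2 and 3 labelled spleen, 263, 5324 and 1066 without LacZ array 1, 2 and 3 labelled tumor, and 1259, 6669 and 699 without Ptpn2 array 1, 2 and 3 labelled tumor. Ugt2b36 was not called after quantile normalization (adjusted p = 0.116) nor Ntrk3 after loess (0.0596), and Ntrk3 and Zfp957 not without LacZ array 1 labelled tumor (0.0649 and 0.0511). Cx3cr1 lost its call without any of 5 of the 12 arrays (up to 0.0883, without LacZ array 3 labelled tumor) and Lag3 without any of 4 (up to 0.0951, without LacZ array 2 labelled spleen).

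For Arhgap5, 4 of 32 cell cycle and 2 of 26 interferon genes were lower in arrays labelled tumor than spleen, each relative to LacZ. Of the cell cycle genes 10 were so over the list alone (median -0.84; limma camera adjusted p = 3.76e-08, 0.64 with an estimated correlation), with Kif11 at -2.61 and the mitotic kinase gene Plk1 at -1.82. Of the interferon genes it was 3 (median -0.66; adjusted p = 1.34e-07, 0.64 estimated), with Ifit1 at -2.08. Hoxc8 differed by 5.86 ± 1.12 (2.20 and -3.67), Tenm2 by 4.90 ± 1.19 and Marveld3 by 4.40 ± 1.20. Their means in Arhgap5 arrays labelled spleen lay near the lowest values (-2.83, -3.40 and -3.72). Slc6a12 differed by -3.45 ± 0.71 (0.33 and 3.78), Ifitm1 by -3.29 ± 0.57 (-2.41 and 0.88) and Khdc1a by -3.11 ± 0.69 (0.78 and 3.89; like Slc6a12 near the lowest values in arrays labelled tumor), and these 6 had adjusted p of 0.00377 to 0.0425. Gzmm differed by -3.05. Of 20 myeloid genes 0 were called and 4 were lower over the list alone (median -0.87; adjusted p = 2.41e-06, 0.64 estimated). Of 14 B cell genes 3 were higher, and 5 over the list alone (adjusted p = 0.0178, 0.64 estimated). Cytokine and MHC class II lists were down (adjusted p = 0.0389 for each, 0.0943 and 0.052 after quantile normalization, adjusted p = 0.964 and 0.64 estimated).

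The Arhgap5 count was 513, 363 up and 150 down. The all-gene median moved from 0.21 to -0.01 with quantile normalization, which kept 193 of these and gave 167 up and 265 down. Loess gave 211 and 276, fewer arrays 55. The count was 252 without LacZ array 2 labelled spleen, 268, 107 and 68 without Arhgap5 array 1, 2 and 3 labelled spleen, 47, 2001 and 132 without LacZ array 1, 2 and 3 labelled tumor, and 92 and 124 without Arhgap5 array 2 and 3 labelled tumor. Tenm2 and Marveld3 were not called after quantile normalization (adjusted p = 0.113 and 0.216) or without any of 6 and 9 of the 12 arrays (up to 0.131 and 0.207, without LacZ array 1 labelled tumor). Ifit1 lost its call without any of 6 arrays (up to 0.0889, without LacZ array 1 labelled tumor), and Khdc1a without Arhgap5 array 3 labelled spleen (0.0545) or tumor.

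For Alk, 7 of 20 myeloid and 7 of 26 interferon genes were lower in arrays labelled tumor than spleen, each relative to LacZ. Of the myeloid genes 9 were so over the list alone (median -1.28; limma camera adjusted p = 2.31e-13, 0.0882 with an estimated correlation), with Apoe at -3.46, Tyrobp at -2.61, Cd68 at -2.32 and C1qa at -2.10. Arg1 differed by -4.16 ± 0.49 (-0.19 and 3.97), Ctsl by -3.78 ± 0.49 (0.12 and 3.90) and Pf4 by -3.46 ± 0.62 (0.61 and 4.08). Chrdl1 differed by 5.60 ± 0.89 (2.19 and -3.42), Hoxc8 by 5.06 ± 1.12 (3.14 and -1.92) and Arhgef15 by 4.87 ± 1.21 (2.09 and -2.79). These 6 had adjusted p of 2.72e-05 to 0.0116, and the target Alk itself differed by 2.46 ± 0.68 (adjusted p = 0.016). Of the interferon genes it was 7 (median -0.57; adjusted p = 4.93e-09, 0.764 estimated), with Oasl1 at -2.69 and Ifit1 at -2.68. Of 13 melanocyte genes 2 were lower and 0 over the list alone (adjusted p = 0.000884, 0.913 estimated). Cell cycle genes were down, 2 called (adjusted p = 0.00108, 0.0816 after quantile normalization). The cytokine list had a median of 0.04 and camera put it down (adjusted p = 0.0234, 0.128 after quantile normalization), and both gave adjusted p = 0.941 estimated.

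The Alk count was 4616, 4209 up and 407 down. After quantile normalization the all-gene median moved from 0.46 to 0.01 and gave 394 up and 497 down, with 532 genes called both ways, and loess gave 207 and 241. The count was 835 without LacZ array 2 labelled spleen, 3074 without Alk array 1 labelled spleen, 759 without LacZ array 1 labelled tumor and 875 without Alk array 1 labelled tumor. Arhgef15 was not called after quantile normalization (adjusted p = 0.0541) or without LacZ array 1 labelled tumor (0.0539), and C1qa not after loess (0.058) or without LacZ array 2 labelled spleen (0.0579) or LacZ array 1 labelled tumor.

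**Figure D3:**
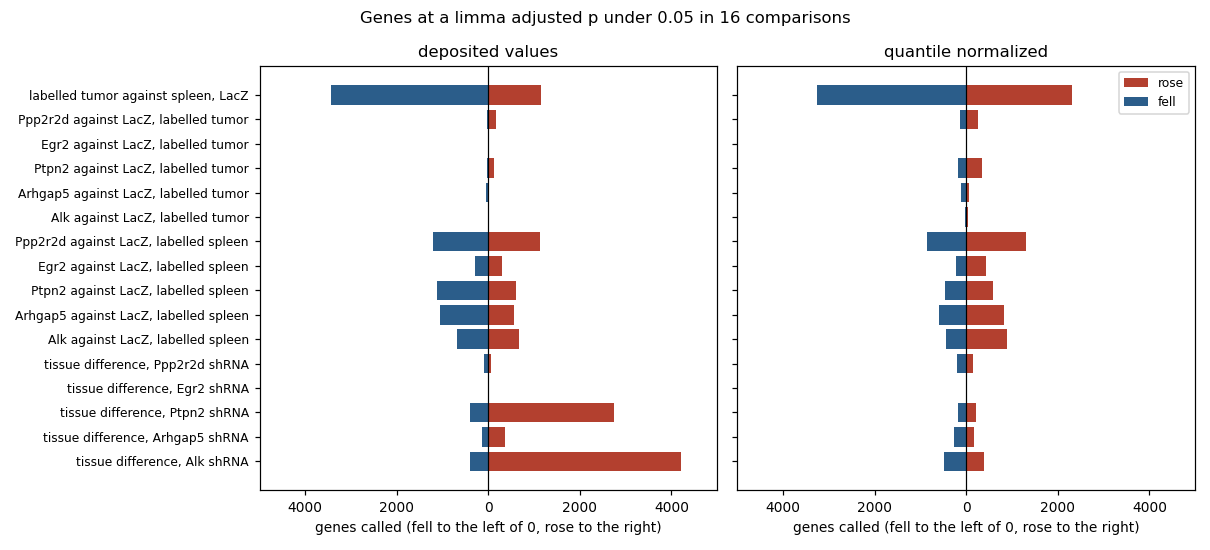
Genes at a limma adjusted p under 0.05 (x axis, falls to the left of 0 and rises to the right) in the 16 comparisons (y axis), from deposited values and after quantile normalization. Rises in the Alk tissue difference number 4209 before and 394 after that step.

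Across the hairpins in arrays labelled tumor, 5 genes changed the same way in at least 3 of the 5 comparisons. Ctse and Ptprv rose with 4 hairpins each (Ppp2r2d, Egr2, Ptpn2 and Arhgap5). Psrc1 and Rnpep fell with Ppp2r2d (-1.63 and -1.58), Egr2 and Arhgap5, and Styk1 with Ppp2r2d, Ptpn2 and Alk. The Y-linked genes Eif2s3y, Kdm5d and Uty, and Orly, rose and Xist fell with Ptpn2 and Arhgap5. Ctse and Ptprv kept apart LacZ and Alk arrays from the other 4 transductions under both labels. Ctse averaged -0.94 and -0.51 in LacZ and Alk arrays labelled spleen and 5.12 to 5.89 in the other transductions, and 1.44 and 1.51 against 5.33 to 5.81 in arrays labelled tumor. Eif2s3y averaged 5.47 to 5.65 in all Ptpn2 and Arhgap5 groups and -3.35 to -1.91 in the others.

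Under simulated unchanged groups sharing the LacZ arrays the median number of such genes was 0 and the highest 27, and 1 of 100 draws reached 5. The number was 45 and 3 without LacZ array 2 and 3 labelled tumor, 8 and 9 without Ptpn2 array 1 and 2 labelled tumor, and 25 after quantile normalization. Psrc1 with the Ppp2r2d hairpin lost its call without any 1 of the 6 arrays (limma adjusted p up to 0.189). In arrays labelled spleen 1091 genes changed the same way in at least 3 comparisons, 381 up and 710 down. In all 5 it was 233, against 0 in every draw. Quantile normalization gave 500 up and 296 down, and loess 571 and 371. The draws hold no offset of the LacZ arrays, which are too few to split, so part of the sharing may come from them.

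**Figure D4:**
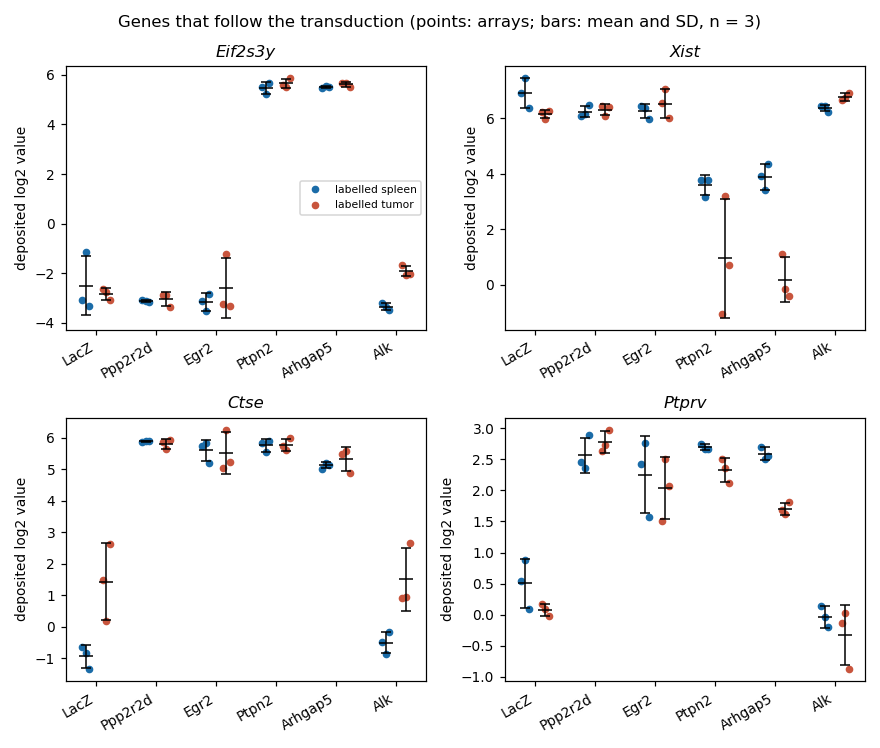
Deposited log2 values of Eif2s3y, Xist, Ctse and Ptprv (y axis) in the 6 transductions (x axis), with points for arrays and bars for mean and SD of 3. Eif2s3y averages 5.47 or more in Ptpn2 and Arhgap5 groups, and Ctse is low in LacZ and Alk groups under both labels.

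Fold changes of all genes in arrays labelled tumor were compared across genes, which are not independent replicates. The Arhgap5 and Alk hairpins gave the highest correlation of the 10 pairs (r = 0.692, 0.63 after quantile normalization), and the shared LacZ arrays alone gave 0.441 on average in simulations. Their covariance was 0.159 against a simulated 0.0709 ± 0.0889 (SD). Ptpn2 and Alk gave r = 0.615, and 0.201 after quantile normalization (covariance 0.215 against 0.155 ± 0.16). Ppp2r2d stood opposite Alk (r = -0.425, -0.213 after quantile normalization, covariance -0.127 against 0.0536 ± 0.0662). Ppp2r2d with Ptpn2 and with Arhgap5 gave r = -0.295 and -0.164, which turned to 0.05 and 0.0793 after quantile normalization (simulated means 0.514 and 0.439), and Egr2 with Alk gave 0.439, which turned to -0.01 (simulated mean 0.371). The other pairs were Ppp2r2d with Egr2 (0.141), Egr2 with Ptpn2 (0.406), Egr2 with Arhgap5 (0.356) and Ptpn2 with Arhgap5 (0.45), against simulated means of 0.463 to 0.499. After quantile normalization these 4 were 0.505, 0.143, 0.152 and 0.249.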

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

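The tests of tissue differences were planned, and the regroupings and the tests of rising calls were chosen after the results were seen. The results below were singled out because a hairpin's effect differed between the labels by limma's test of the difference itself. For Ppp2r2d 143 genes differed, with Dtx1 at 4.11, Gzmf 3.89, Cphx3 3.83, Grb10 -5.28, Klrb1a -4.74 and Igfbp2 -4.58. For Ptpn2 3151 genes differed, with Ntrk3 at 4.99, Ugt2b36 4.96, Zfp957 4.93, Gbp2 -3.96, Gpr137b -3.06 and Iigp1 -3.01. But limma with only its 12 arrays in the fit called 0 (3936 at unadjusted p under 0.05). For Arhgap5 513 genes differed, with Hoxc8 at 5.86, Tenm2 4.90, Marveld3 4.40, Slc6a12 -3.45, Ifitm1 -3.29 and Khdc1a -3.11. For Alk 4616 genes differed, with Chrdl1 at 5.60, Hoxc8 5.06, Arhgef15 4.87, Arg1 -4.16, Ctsl -3.78, Pf4 -3.46 and Alk itself 2.46. Among the rising genes most had a hairpin mean near the lowest values in arrays labelled spleen, so sizes and order are not exact.

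Regrouping the arrays at random within each label gave as many genes in 7 of 100 regroupings for Ppp2r2d (143 genes, highest other 2419). For Ptpn2 it was 6 (3151, highest other 4646), for Arhgap5 2 (513, highest other 1025) and for Alk 1 (4616, highest other 3985). The last 2 shares are under 0.05 but not adjusted over the hairpins, so chance is excluded for none. For Egr2 the count was 0, which all 100 regroupings reached (highest other 1099). Regroupings that call several times the real count point to a structure of the samples.

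In the Ptpn2 and Alk tissue differences rising calls outnumbered falling ones, 2747 to 404 and 4209 to 407, and dim genes held most of them: 98.2% and 97% of the calls among dim genes rose. A candidate explanation is a difference between the arrays' value distributions, since after quantile normalization 212 rising calls were left for Ptpn2 and 394 for Alk. The 3 arrays with a raised floor stay open too: without them 323 were left for Ptpn2 and 3585 for Alk, but without LacZ array 2 labelled spleen alone 417 and 657. Leaving out LacZ array 1 labelled tumor, which has the lowest floor of all 36 arrays (-4.51), left 229 and 661. The Alk arrays labelled tumor, with floors of -2.37 to -1.88, were not among the 3 left out. The 3585 calls left for Alk therefore do not weigh against floor differences as a cause. A difference in how the hairpins act in the 2 tissues stays open as untested.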

How the results depend on the processing

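Tests with quantile normalization or without the outlying Ptpn2 array or the 3 arrays of raised floor were chosen after seeing the results, others before. Where a value below moved, the cause was not tested. Signal over background limits what can be read for dim genes: the mean level of Alk lay at percentile 25.1 of all genes.

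With fewer arrays in the fit, 1862 genes were called between the labels of LacZ. Arrays labelled tumor gave 36, 2, 28, 20 and 0 for Ppp2r2d, Egr2, Ptpn2, Arhgap5 and Alk. In arrays labelled spleen it was 4479, 2169, 3852, 4131 and 3444 in the same order. Tissue differences were 63 for Ppp2r2d, 0 for Ptpn2 and 55 for Arhgap5, and 2 genes were shared. In arrays labelled spleen the targets Egr2 (-1.19, adjusted p = 0.0152), Ptpn2 (-0.79, adjusted p = 0.0341) and Alk (-1.32, adjusted p = 0.0254) were then called in their own groups. With only genes above the 40th percentile the counts were 344 for Ppp2r2d and 8 for Alk in arrays labelled tumor, 692 and 748 for the Ptpn2 and Alk tissue differences, and 8 shared genes.

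After cyclic loess the counts in arrays labelled tumor were 439, 18, 431, 170 and 54 for Ppp2r2d, Egr2, Ptpn2, Arhgap5 and Alk. Tissue differences were 467 for Ppp2r2d, 2 for Egr2, 300 for Ptpn2 and 448 for Alk, 23 genes were shared, and Ptpn2 in its own labelled spleen group was called (-0.78, adjusted p = 0.000268). After quantile normalization they were 392, 11, 528, 169 and 67 in arrays labelled tumor, 1049 for Ptpn2 in arrays labelled spleen, and 365, 15, 404 and 891 for the Ppp2r2d, Egr2, Ptpn2 and Alk tissue differences, with 25 shared genes. Ptpn2 in its own labelled spleen group was called (-0.84, adjusted p = 4.32e-05). Correlations of effects turned to 0.05 for Ppp2r2d with Ptpn2, 0.0793 for Ppp2r2d with Arhgap5 and -0.00822 for Egr2 with Alk, and moved to -0.213 for Ppp2r2d with Alk, 0.201 for Ptpn2 with Alk, 0.505 for Ppp2r2d with Egr2, 0.143 for Egr2 with Ptpn2, 0.152 for Egr2 with Arhgap5 and 0.249 for Ptpn2 with Arhgap5. Quantile normalization without dim genes gave tissue differences of 409 for Ppp2r2d, 13 for Egr2, 435 for Ptpn2 and 918 for Alk.

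Array weights ran from 0.0645 for Egr2 array 2 to 58 for Alk array 2, both labelled tumor, and their estimation stopped before it converged. With them the counts were 5284, 1374, 37, 2798 and 12060 in arrays labelled tumor, 4022, 1602, 4001, 3931 and 3111 in arrays labelled spleen, and 1864, 1351, 1754, 5074 and 8656 for the tissue differences, with 966 shared genes. A replicate block by transduction gave 92 for the Ppp2r2d and 880 for the Arhgap5 tissue difference.

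Without the outlying Ptpn2 array the counts in arrays labelled tumor were 311 for Ppp2r2d, 57 for Ptpn2 and 10 for Alk, with tissue differences of 13 for Egr2 and 1259 for Ptpn2 and 8 shared genes. Without the 3 arrays of raised floor they were 535 for Ppp2r2d, 907 for Ptpn2, 106 for Arhgap5 and 4021 for Alk, with tissue differences of 252 for Ppp2r2d, 9 for Egr2, 636 for Ptpn2 and 840 for Arhgap5, and 25 shared genes. With the mean of all probe sets 3 genes were called for Egr2 in arrays labelled tumor and 6 for its tissue difference, and Gpnmb turned to -0.001 for Ppp2r2d (adjusted p = 0.999). Other probe sets gave Egr2 -1.43 (adjusted p = 0.021) in its own labelled spleen group and 0.093 in its labelled tumor group, Ptpn2 -1.02 (adjusted p = 0.0496), and Arhgap5 -0.60 and -0.64, both in their labelled spleen groups. Of 97 list calls 1 held with an estimated correlation, 91 with the mean of probe sets, 75 after loess, 72 after quantile normalization and 97 with the replicate block.

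Leaving out 1 array gave 3399 to 5361 genes between the labels of LacZ. Arrays labelled tumor gave 54 to 814 for Ppp2r2d, 3 to 5 for Egr2, 49 to 4003 for Ptpn2, 27 to 194 for Arhgap5 and 0 to 1691 for Alk. In arrays labelled spleen these were 826 to 2432, 90 to 629, 476 to 1976, 518 to 2374 and 401 to 1566. Tissue differences were 75 to 217, 0 to 590, 263 to 6669, 47 to 2001 and 759 to 5534, and shared genes 3 to 45. The targets in their own groups, labelled spleen and then tumor, were -1.71 to -1.12 and -0.26 to 0.012 for Ppp2r2d, -1.57 to -0.95 and -0.49 to 0.274 for Egr2, and -0.99 to -0.52 and -0.57 to -0.15 for Ptpn2. They were 0.13 to 0.63 and -0.67 to -0.17 for Arhgap5 and -1.85 to -0.98 and 0.74 to 1.69 for Alk. Of 269 named results 26 lost their call with the mean of probe sets, 17 after loess, 60 with fewer arrays, 11 with array weights, 6 with the replicate block, 15 after quantile normalization and 0 with the dim gene filter. Leaving out 1 array ended 215 of 1890 calls.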

Other observations

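All tests in this part were chosen after the results were seen, except planned list counts.

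Genes of melanin synthesis, inhibitory receptors and granzymes were high in the arrays labelled spleen. Normalization between arrays is argued against, since the melanocyte list still differed by -3.57 after quantile normalization. Melanoma RNA carried over into otherwise unmoved T cells is argued against by the 42 genes of the inhibitory receptor and cytotoxic lists. They differed by a median of -2.0 between LacZ arrays labelled tumor and spleen (-0.96 with 2 standard errors added), and 31 lay below -1. Every median over them of an array labelled spleen lay above every one labelled tumor, by at least 0.885. Neither value met its bound of more than 1 beyond its spread, so the carry-over is not excluded. Also, 10 of 19 naive and memory genes rose while T cell identity genes had a median of -0.21. An exchange of the tissue labels stays open, since the higher melanocyte median in all 18 arrays labelled spleen (2.85 or more, against -0.90 or less) only restates the pattern. Whether cells from the labelled tissues truly differed this way was not tested, and no array was relabelled.

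Of the 25 genes called with at least 2 hairpins in arrays labelled tumor, 5 lie on X or Y and 19 on autosomes. For the 5, donor sex may differ between transductions. Only in Ptpn2 and Arhgap5 did the median of 3 Y-linked genes exceed 0 in every array under both labels. Sex as the whole cause of the 19 is argued against. Of these 15, Ctse and Ptprv among them, were called with a hairpin whose Y-linked genes were as low as in LacZ. A differing genetic background was tested first on the 19, and the most within 50 neighbouring measured genes was 2, as in the median of 10000 random sets (permutation p = 0.614). A second test, added after the first gave no excess, took the 5 genes called with at least 3 hairpins: Ctse, Ptprv and Rnpep lie on chromosome 1 within 54 measured genes, which 5 of 10000 random sets matched (permutation p = 6e-04, not adjusted for that choice). Genetic background, the shared LacZ arrays and an effect of the hairpins stay open.

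With 3 arrays against 3 there are 10 splits, so no share under 0.05 can be reached. As many genes were called by 1 split between the labels of LacZ (4589, highest other 278) and by 1 for Ppp2r2d labelled tumor (181, highest other 25). For arrays labelled tumor 3 splits did so for Egr2 (5, highest other 363), 2 for Ptpn2 (139, highest other 5627), 2 for Arhgap5 (67, highest other 182) and 2 for Alk (1, highest other 413). The highest other split of these 4 put LacZ arrays 1 and 3 against LacZ array 2, and counts several times the real one point to a structure of the samples. In arrays labelled spleen 1 split did so for each hairpin. The highest other was 4 for Egr2 (588) and 0 for Ppp2r2d (2334), Ptpn2 (1743), Arhgap5 (1617) and Alk (1347).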
